A study of Caenorhabditis elegans with 4 samples.

How the data were processed

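Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on whole Caenorhabditis elegans grown to the L4 larval stage, per the labels' protocols. The target was LAG-1, the worm's CSL-family DNA-binding protein, which acts in the Notch pathway. The series held 4 libraries: 1 immunoprecipitation (IP) with an antibody to FLAG, 2 with an antibody to GFP, which the labels number 2 and 3, and 1 input DNA library. The 3 IP libraries are called FLAG 1, GFP 2 and GFP 3 here. The design text names the 3 IPs as biological replicates.

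Each IP had its own deposited peak list, and the input entered only through the peak calling. Per the file headers, the authors called peaks with MACS 2.1.0.20140616 in each IP alone, against the same input library, at a q-value limit of 0.05 with summit splitting. Per the file headers, 1 tag was kept per position, and the larger library was sampled down at random to the size of the smaller. The tag size was 49 bp. The fragment length used by the caller was 53 bp in FLAG 1, 58 bp in GFP 2 and 48 bp in GFP 3, per the file headers. These lengths are close to the tag size, as can happen when the caller measures an artefact of read length in place of the fragments. The pileups, folds, summits, peak widths and pileup limits rest on these lengths, which could not be estimated again from peak lists. The genome build was ce10, per the submitters' processing notes, and the aligner is not given in the sources used here.

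The deposited columns hold, per summit, a pileup, a fold enrichment and 2 significance values. The pileup is a signal in tags, counted by the authors' caller after extension of each tag to the fragment length. The fold enrichment is the ratio of the pileup plus 1 to the caller's background plus 1, as deposited. The significance columns hold the −log10 of the p-value and of the q-value, as deposited. The background was recovered from the pileup and fold. A Poisson p-value from that background differed from the deposited −log10 p-value by at most 6.08e-05, and the lowest recovered background in each list equalled the genome-wide mean expected from its tags (7.18, 4.42 and 5.02 tags for FLAG 1, GFP 2 and GFP 3). Positions are 1-based ce10 coordinates. Fold enrichment was used to describe, rank and filter peaks within a list only, because depth and fragment length set a different highest possible fold in each list.

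Peaks with several summits take several lines in the lists, and the summit with the highest fold stood for each peak here. Peaks were kept with a fold above 2 and a q-value under 0.05, as the design text states. Overlap meant at least 1 bp. Overlaps were compared with 100000 random placements in which each peak kept its length and chromosome and fell uniformly between the first and last base of any deposited peak on that chromosome. Alternatives used 10000 placements, or 1000 for the 50% overlap rule. The p-values are one-sided, with Benjamini-Hochberg adjustment over the 6 ordered pairs of lists. Peaks that overlapped or touched were merged into regions. Within each list, the median log2 fold of peaks in regions of all 3 libraries was compared with that of peaks in regions of that library alone, by a two-sided permutation test with 100000 resamples, adjusted over the 3 lists, with 95% bootstrap intervals from 2000 draws. Shares carry 95% Wilson intervals. Intervals cover counting error only, over peaks that are not independent of each other.

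A background over 3 times the genome-wide mean is called raised, and this limit was chosen after seeing the data. The first 25 regions of all 3 libraries by mean percentile of fold within each list are named, as are the first 5 in FLAG 1 alone and the first 5 in both GFP libraries but not FLAG 1. This rule, the alternatives and the tests were fixed before the data were examined, except where stated. In simulations, lists with the numbers and lengths of the FLAG 1 and GFP 2 peaks were both placed at random. There 20 planted overlaps gave a mean excess of 20.0 and passed in 100 of 100 simulations. With 0 planted, 2 of 100 passed. Both lists were placed uniformly, as the test itself assumes, so the crowding of the real peaks was not simulated.

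All 3 lists share 1 input library, and reads were not used here, so the part of the overlap that shared input could give was not simulated, and part of the excess may come from it. The p-values compare these libraries and their peaks, not the antibodies in general. No gene annotation or genome of the ce10 build was used here, so the planned tests of gene lists (including Notch targets), of the LAG-1 motif and of positions in genes were not run, and chromosome shares were not set against chromosome length. The gene table at hand is of the WBcel235 assembly, and builds were not mixed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.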

Results

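To map where LAG-1 sits on chromatin in whole L4 worms, the study set 3 immunoprecipitations against input DNA, 1 with a FLAG antibody and 2 with a GFP antibody. FLAG 1 held 14317856 tags, of which 12186235 remained after duplicate removal. GFP 2 held 8239811 tags and kept 6858855. GFP 3 held 12914175 tags and kept 9404288. The input held 24598804 tags and kept 20457188. The share of tags lost as duplicates was highest in GFP 3, at a rate of 0.27, against 0.15 in FLAG 1 and 0.17 in both GFP 2 and the input.

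The first question was how many places each antibody enriched. GFP 2 gave 805 peaks above 2-fold, FLAG 1 gave 671 and GFP 3 gave 258. Peaks were narrow, with quartiles of width of 69 and 218 bp in FLAG 1, 78 and 215 bp in GFP 2 and 71.3 and 226 bp in GFP 3. The median fold enrichment over input was 3.18 in FLAG 1 (quartiles 2.69 and 4.05), 3.23 in GFP 2 (quartiles 2.74 and 4.06) and 2.35 in GFP 3 (quartiles 2.16 and 3.13). The strongest peak reached 11.3-fold in FLAG 1, 19.8-fold in GFP 2 and 15.5-fold in GFP 3. The lists themselves were longer, because 204 of the 875 deposited peaks of FLAG 1, 42 of the 847 of GFP 2 and 141 of the 399 of GFP 3 had a fold of 2 or less.

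The peaks fell into a low-background and a raised-background class. In FLAG 1, 650 of the 671 peaks lay where the local background was at most 3 times the genome-wide mean, and 21 peaks (3.13%, 95% interval 2.06 to 4.74) lay above it. In GFP 2 the raised-background share was 29.7% (239 peaks, interval 26.6 to 32.9), and in GFP 3 it was 70.5% (182 peaks, interval 64.7 to 75.8). GFP 3 thus had 76 low-background peaks. The 2-fold limit shapes these shares, since all 204 FLAG 1 peaks that it removed had a raised background. Among all deposited peaks, 225 of 875 in FLAG 1, 281 of 847 in GFP 2 and 323 of 399 in GFP 3 had one. Low-background peaks had a median fold of 3.18 in FLAG 1, 3.64 in GFP 2 and 3.66 in GFP 3, and raised-background peaks 2.11, 2.59 and 2.24. Raised-background peaks were crowded: 71.5% of the 442 in the 3 lists lay in 20000 bp windows that held at least 5 of them, against 16.9% of the 1292 low-background peaks. The densest such window held 27 peaks, between 109247 and 114239 on chromosome X. Peaks of different lists at the same place were counted separately, which can raise these counts.

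**Figure D1:**
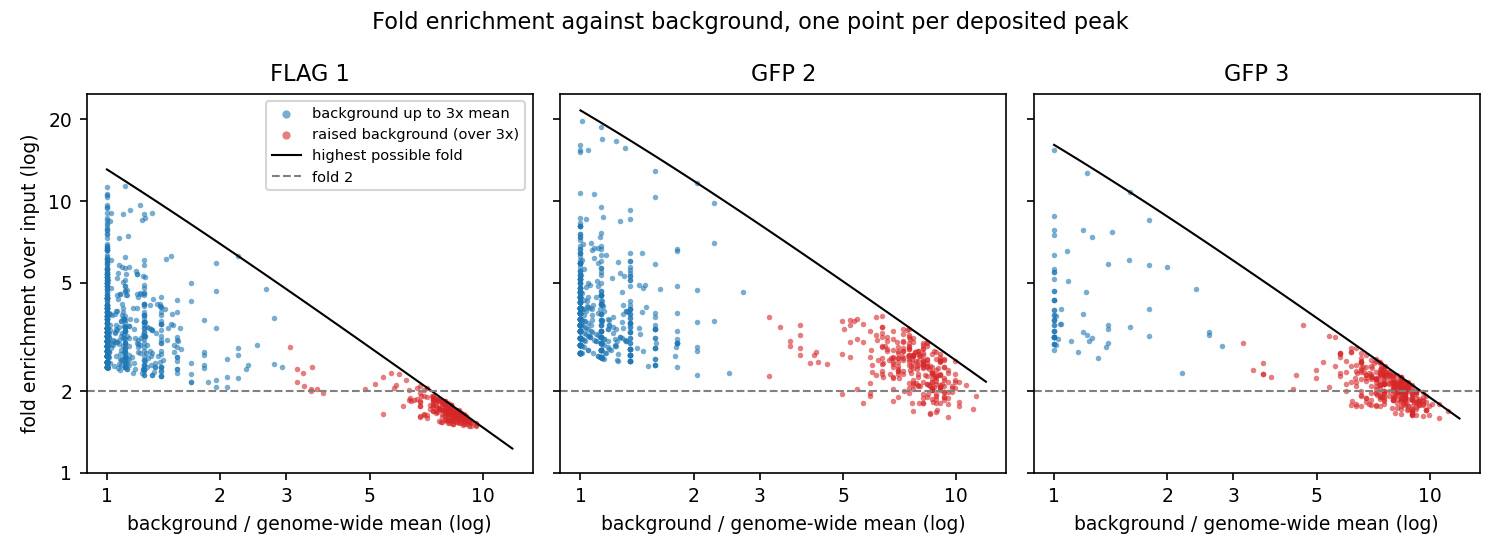
Fold enrichment over input (log axis) against the caller's background relative to the genome-wide mean (log axis), 1 point per deposited peak in each library. The dashed line marks 2-fold and the solid line the highest fold that 1 tag per position and strand allows. Low-background peaks spread up to 11.3, 19.8 and 15.5-fold, and raised-background peaks have median folds of 1.69, 2.48 and 2.07 at median pileups of 94.3%, 73.3% and 87.5% of the limit.

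The second question was whether the antibodies found the same places. Of the FLAG 1 peaks, 36.96% (248 of 671) overlapped a GFP 2 peak, against 0.282% expected from random placement. In the other direction, 30.1% of the GFP 2 peaks (242 of 805) overlapped FLAG 1, against 0.241%. GFP 3 peaks overlapped GFP 2 in 84.1% of cases (217 of 258, random 0.298%) and FLAG 1 in 31.4% (81 of 258, random 0.244%). The lists differ in length, and with the 258 highest folds of each list these shares were 28.3% (73 of 258) and 16.7% (43 of 258). This cut left GFP 3 whole, with 182 of its 258 peaks in raised background. In GFP 2 it kept the highest folds, and raised-background peaks there were weaker (median fold 2.59 against 3.64 at low background). The cut thus changed the mix of background as well as the length, so the lower shares cannot be put down to length alone. Of FLAG 1 and GFP 2 peaks, 11.8% (79) and 25.2% (203) overlapped GFP 3, against 0.0885% and 0.0913%. Each of the 6 shares had an adjusted permutation p of 1e-05, the smallest that 100000 placements can give.

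The overlaps were also computed in the low-background class. With raised-background peaks left out, 88.2% of the GFP 3 peaks (67 of 76) overlapped FLAG 1 and 94.7% (72 of 76) overlapped GFP 2, so the few low-background places found in GFP 3 were nearly all found in the other libraries. FLAG 1 and GFP 2 overlapped in 35.5% of FLAG 1 peaks (231 of 650) and 40.1% of GFP 2 peaks (227 of 566). The share of GFP 2 peaks found in GFP 3 was then 12.01% (68 of 566). Adjusted permutation p was 0.0001 for each, the smallest that 10000 placements can give. This split was chosen after seeing the data.

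Merging gave 1255 regions, of which 76 held a peak of every library, against a mean of 0.00569 and at most 1 in 100000 random placements (permutation p = 1e-05). Of the 76, 64 had a low background and 12 a raised one. A further 155 regions, all of low background, held peaks of FLAG 1 and GFP 2 only. GFP 2 and GFP 3 alone shared 124 regions, of which 118 had a raised background. Single-library regions numbered 422 in FLAG 1, 437 in GFP 2 and 41 in GFP 3. No region joined FLAG 1 and GFP 3 without GFP 2. The count of regions in all 3 libraries depended on GFP 3: without it, 231 regions were in both other libraries, and without FLAG 1 there were 201.

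**Figure D2:**
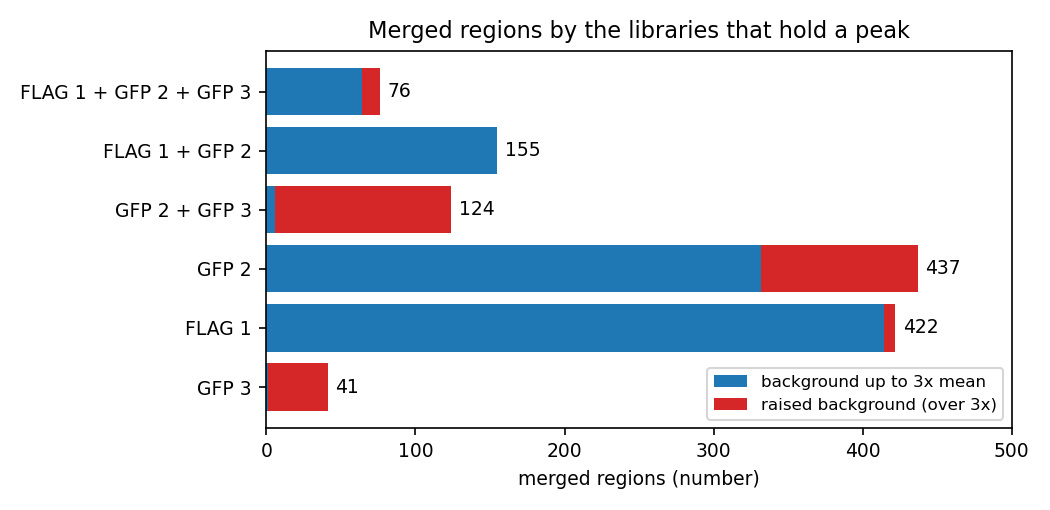
Number of merged regions by the set of libraries that hold a peak in them, split by background. The 76 regions of all 3 libraries and the 155 of FLAG 1 with GFP 2 are mostly or wholly of low background, and 118 of the 124 regions of the GFP libraries alone are of raised background.

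Distances between summits were measured in the regions of all 3 libraries. In the 64 of low background, the median distance between FLAG 1 and GFP 3 summits was 17.5 bp (quartiles 11 and 42.8), and 50 of the 64 pairs lay within 50 bp. It was 30 bp between FLAG 1 and GFP 2 (quartiles 7.0 and 64.3, 45 pairs within 50 bp) and 21 bp between GFP 2 and GFP 3 (quartiles 8.75 and 67.8, 45 pairs within 50 bp). In the 12 of raised background the medians, in the same order, were 4, 6 and 4 bp, so short distances were not particular to low background. The distance expected by chance within overlapping peaks was not computed.

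The region that ranked first over the 3 libraries lay on chromosome I, from 10587961 to 10588856. Its fold was 11.3 in FLAG 1, 18.8 in GFP 2 and 15.5 in GFP 3, and its summits were at 10588352, 10588359 and 10588355. The second lay on chromosome III, from 9793447 to 9794155, with folds of 9.70, 15.7 and 12.7 in the same order and summits at 9793825, 9793830 and 9793825. The third, on chromosome III from 6344561 to 6345109, had folds of 9.66, 15.1 and 8.81. The fourth, on chromosome V from 15133610 to 15134248, had folds of 10.5, 16.05 and 7.48. The fifth, on chromosome III from 3630259 to 3630873, had folds of 9.06, 16.6 and 7.36. A region on chromosome X from 14790191 to 14790884 held the highest fold of GFP 2, at 19.8, with 9.0 in FLAG 1 and 5.80 in GFP 3. A region on chromosome I from 12483415 to 12484195 had folds of 6.29, 11.7 and 10.8. Its pileups of 106, 116 and 96 were the highest that 1 tag per position and strand allows in each library, so these folds are at their ceiling.

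The other 18 of the first 25 regions were spread over all 6 chromosomes. On chromosome I they were 2914163 to 2914827, 14276536 to 14276927 and 4587058 to 4587783. On chromosome II they were 7277232 to 7277738 and 13161052 to 13161392, and on chromosome III 9565833 to 9566254. Chromosome IV held 6096741 to 6098374, 7389813 to 7390047, 16656142 to 16656694 and 2726485 to 2726821. Chromosome V held 13657197 to 13657846, 11769907 to 11770641, 9856140 to 9856528, 13243195 to 13243594 and 5763789 to 5764203. Chromosome X held 13104771 to 13105293, 15741247 to 15741950 and 16929777 to 16931901. Over the 25 regions, folds ran from 4.04 to 11.3 in FLAG 1 (median 6.26), from 5.44 to 19.8 in GFP 2 (median 10.7) and from 3.14 to 15.5 in GFP 3 (median 5.88). None of the 25 had a raised background. The pileup was at 80% or more of the highest value that 1 tag per position and strand allows in 9 of them in FLAG 1, 8 in GFP 2 and 4 in GFP 3, which bounds the folds of these.

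**Figure D3:**
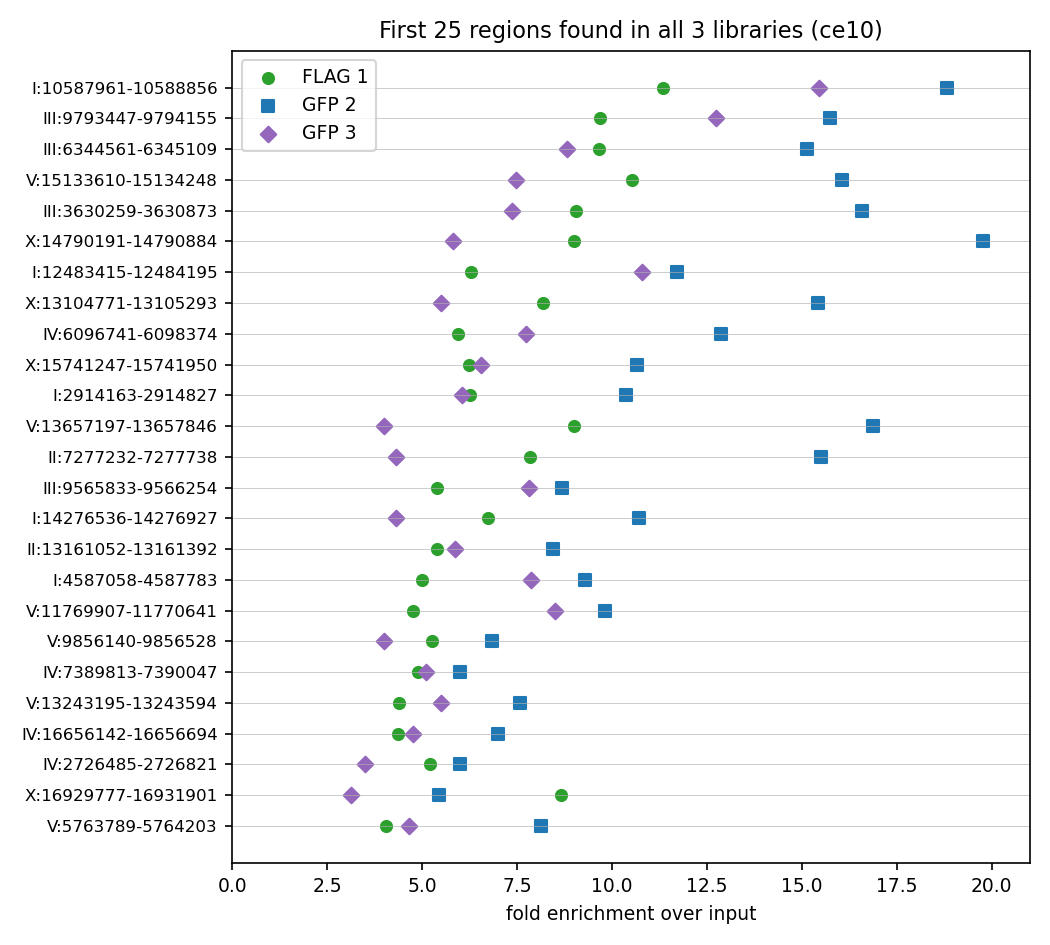
Fold enrichment over input in each library for the first 25 regions found in all 3 libraries, ordered by mean percentile within the lists, with ce10 positions on the vertical axis. Folds run from 3.14 to 19.8, and their scale differs between libraries because depth and fragment length set different upper limits.

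The next comparison asked whether shared peaks were the stronger ones within each list. In GFP 2, peaks in regions of all 3 libraries had a median fold of 5.88 (n = 77) against 3.14 for peaks of GFP 2 alone (n = 437), a log2 difference of 0.91 (95% interval 0.71 to 1.09, adjusted permutation p = 1.5e-05). In GFP 3 the medians were 3.49 (n = 83) and 2.23 (n = 41), a log2 difference of 0.65 (interval 0.51 to 0.80, adjusted permutation p = 1.5e-05). Of the 41 unshared peaks, 40 had a raised background, where the median highest possible fold was 2.37 over all such GFP 3 peaks, while 69 of the 83 shared peaks had a low one. The GFP 3 result did not hold by −log10 q (difference -0.46, adjusted permutation p = 0.51), when sharing meant 1 other library (0.12, adjusted permutation p = 0.089) or above 3-fold (0.44, adjusted permutation p = 0.21, 5 unshared peaks). In FLAG 1 the medians were 3.29 (n = 88) and 3.12 (n = 422), and the log2 difference of 0.08 (interval -0.03 to 0.26) did not pass (adjusted permutation p = 0.199). With raised-background peaks left out, the FLAG 1 difference was 0.22 (adjusted permutation p = 0.0008) and that of GFP 2 was 0.96 (adjusted permutation p = 0.0002). The GFP 3 comparison then had too few unshared peaks. With all deposited peaks, the difference changed sign in FLAG 1 (-0.82) and GFP 2 (-0.18).

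Some strong peaks were seen with FLAG alone. The strongest was on chromosome X from 1503769 to 1504578, with a fold of 10.4. The next were on X from 4147334 to 4148040 (fold 9.05), on X from 17419791 to 17420727 (fold 8.68), on II from 8746936 to 8747576 (fold 8.42) and on III from 6415545 to 6416029 (fold 6.85). All 5 had a background within 2% of the genome-wide mean. With 1 FLAG library, antibody and library cannot be told apart here. Of the regions of both GFP libraries without FLAG 1, the first by mean percentile was on X from 12362968 to 12363254, with folds of 4.50 in GFP 2 and 3.66 in GFP 3. The next were on I from 14462995 to 14463127 (4.24 and 3.66), on II from 5543606 to 5543751 (4.43 and 2.99), on II from 8185111 to 8185200 (4.05 and 2.83) and on V from 5283287 to 5283351 (3.50 and 3.50). The one on V had a raised background, 4.89 times the genome-wide mean, and the other 4 did not.

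Peaks lay on all 6 chromosomes, and the share on X differed between the lists. It was 14.8% in FLAG 1 (99 peaks, 95% interval 12.3 to 17.6), 21.9% in GFP 2 (176 peaks, interval 19.2 to 24.9) and 29.8% in GFP 3 (77 peaks, interval 24.6 to 35.7). Fisher's exact test, two-sided and adjusted over the 3 pairs of lists, gave 0.00071 for FLAG 1 against GFP 2, 1.1e-06 for FLAG 1 against GFP 3 and 0.012 for GFP 2 against GFP 3. These tests were added after seeing the data and compare single libraries. They also count peaks as independent, although peaks crowd together and the lists share many places, so the p-values may be too small. Among low-background peaks the shares were 14.9%, 21.2% and 31.6%, with adjusted exact p of 0.0081, 0.0017 and 0.056. Of the 76 regions in all 3 libraries, 21 were on X (27.6%, interval 18.8 to 38.6), 16 on IV, 13 on V, 10 on III, 9 on I and 7 on II.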

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

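Of the tests in this part, all were chosen only after the results were seen. The deposited lists hold peaks that the comparisons did not use, because their fold over input was 2 or less: 204 in FLAG 1, 42 in GFP 2 and 141 in GFP 3. Each passed the caller's q-value limit against input, and each lay in raised background. The limit itself favours this, because a fold that low passes it only where the background is high.

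The pattern these peaks belong to is that raised-background regions passed 2-fold in both GFP lists and mostly not in FLAG 1. Of the 118 raised-background regions shared by the GFP lists alone, 67.8% (95% interval 58.9 to 75.6) hold a deposited FLAG 1 peak with a fold of 2 or less. For these the lists differ in passing the fold limit, not in whether a peak was called. Such FLAG 1 peaks may arise without enrichment, as weighed below. They therefore cannot decide whether binding was seen with GFP and absent with FLAG. A candidate explanation is the limit that duplicate removal sets, which is 106, 116 and 96 tags of pileup for FLAG 1, GFP 2 and GFP 3, equal to the highest pileup in each list. Of all 225 deposited FLAG 1 peaks with raised background, 79.6% (interval 73.8 to 84.3) lie where even that pileup gives a fold of 2 or less, against 0 of 281 in GFP 2 and 18 of 323 in GFP 3, and the median highest possible folds are 1.81, 3.31 and 2.37. Whether repeated sequence, saturated in input and IP alike, accounts for these peaks with no enrichment stays open. Full saturation of both, with the input sampled down, would give folds of 1.67, 2.93 and 2.15 without enrichment. The median folds of all raised-background peaks were 1.69, 2.48 and 2.07, so GFP folds above 2 there can arise without enrichment. The median pileup was 1.21 times that expected without enrichment in FLAG 1 (quartiles 1.07 and 1.37), 1.45 times in GFP 2 (0.997 and 1.80) and 1.22 times in GFP 3 (1.025 and 1.45). However, 13.3%, 22.8% and 17.3% of the input values there were at the limit expected for the sampled input, where this expectation fails.

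A second pattern is the short GFP 3 list. Fewer tags are argued against as its cause, because GFP 3 kept 137% of the tags that GFP 2 kept and gave 258 peaks against 805. A less complex or less enriched IP may be the reason, and its redundant rate of 0.27 was the highest, but with 1 such library this cannot be told apart from a difference in the worms.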

How the results depend on the processing

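Every one of the 84 alternative overlap shares stayed above random placement, with adjusted permutation p of at most 0.001, the smallest that 1000 placements can give. The shares with GFP 3 moved by over 1.5 times. GFP 3 in GFP 2 fell from 84.1% to 28.3% with lists of equal length. That cut is by fold and also shifts GFP 2 away from raised background. GFP 3 in FLAG 1 went from 31.4% to 16.7% with lists of equal length, 75% above 3-fold, 75.9% above 4-fold, 61.7% with no fold filter and 56.8% with background at the genome-wide mean. GFP 2 in GFP 3 went from 25.2% to 13.03%, 13.6% and 9.41% above 3-fold, above 4-fold and at the genome-wide mean. FLAG 1 in GFP 3 went from 11.8% to 30.6% with no fold filter and 6.50% at the genome-wide mean. Peak counts moved with the threshold. In the order FLAG 1, GFP 2 and GFP 3, they were 389, 476 and 68 above 3-fold, 180, 214 and 29 above 4-fold, and 165, 239 and 44 at a −log10 q above 10. At a −log10 q above 5, FLAG 1 kept 331 and GFP 2 kept 479. In settings added after seeing the data, they were 323, 255 and 37 with background at the genome-wide mean, and GFP 3 had 399 with no fold filter and 76 without raised background. Regions in all 3 libraries numbered 50 and 22 above 3-fold and 4-fold, 45 and 19 at a −log10 q above 5 and 10, 40 with lists of equal length, 206 with no fold filter and 17 with background at the genome-wide mean, against 76. Leaving out a library gave 76 (without GFP 2) to 231 (without GFP 3). With raised-background peaks left out before merging, 61 regions held all 3 libraries.

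The comparison of shared with unshared peaks kept its call in 6 of 14 alternatives. In FLAG 1 the difference passed the permutation test by −log10 q (2.31, adjusted permutation p = 0.0009), above 3-fold (0.20, p = 0.011, but bootstrap interval -0.01 to 0.47) and without raised background (0.22, p = 0.0008), and reversed with no fold filter (-0.82, p = 0.00015). In GFP 2 it reversed only with no fold filter (-0.18, adjusted permutation p = 0.00015). In GFP 3 it reversed by −log10 q (-0.46, adjusted permutation p = 0.51) and no longer passed when sharing meant 1 other library (0.12, p = 0.089, interval 0.04 to 0.20) or above 3-fold (0.44, p = 0.21, interval 0.26 to 0.72), where 5 unshared peaks were left. Other causes were not tested. The 8 alternative X shares stayed within the intervals of the main ones, but the exact test of GFP 2 against GFP 3 no longer passed above 3-fold (adjusted exact p = 0.17) or without raised background (0.056). The other settings foreseen for motif, gene lists and gene positions were not run, for want of a genome of the build. No paired analysis was possible because the FLAG and GFP groups share no replicate number and the input has no peak list. GFP 2 kept the fewest tags.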

Other observations

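The strongest places, ranked after seeing the data, were largely common to both antibodies. Of the 25 low-background peaks with the highest fold in GFP 2, 23 overlapped a FLAG 1 peak and 20 a GFP 3 peak. Of the 25 highest in FLAG 1, 21 overlapped GFP 2 and 10 overlapped GFP 3. All 25 of the highest in GFP 3 overlapped both other lists.

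The last pattern weighed is the overlap of FLAG 1 and GFP 2 peaks itself. Of its tests, the one on the shared input was set before its result was seen, and the others after. Sequence with raised background is argued against as its whole source, because 35.5% of FLAG 1 peaks still overlapped GFP 2 without raised-background peaks. Only 21 of the 671 FLAG 1 peaks had a raised background, so leaving them out could move the share little. Repeated or unevenly mapped sequence with a background of up to 3 times the genome-wide mean stayed among the rest and was not tested. Chance dips in the shared input stay open. Among peaks with background at the genome-wide mean, 25.7% of those in FLAG 1 (83 of 323) overlapped such a peak of GFP 2, against 0.0807% at random (adjusted permutation p = 0.0001, the smallest possible). The bound set beforehand was met, but it was a wrong one: the caller's background cannot fall below that mean, so these are places where the local input was at or below it, and sites at a dip are kept among them. Signal that any IP of these worms would give, for example at open chromatin, cannot be told apart from LAG-1 binding, because the lists used include 0 control immunoprecipitations.

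A hypothesis was that low-background regions of all 3 libraries lie near each other, with both tests set before their results were seen. Of the 64 regions, 7 had another within 10000 bp, against a mean of 0.874 in 100000 random placements (permutation p = 0.00093, one-sided). Draws of 64 from all 972 low-background regions gave a mean of 4.04 (permutation p = 0.15), so the uneven spread of low-background regions in general may account for it. The closest group was on chromosome IV, where regions at 6095030 to 6095373, 6096741 to 6098374 and 6099700 to 6100272 were 1367 and 1325 bp apart.

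Peaks also began within the first 300 bp of chromosomes: 3 in FLAG 1, 4 in GFP 2 and 5 in GFP 3. All 3 libraries had one on III, IV and X, with folds of 2.17 to 3.73 and backgrounds of 2.23 to 3.85 times the genome-wide mean. The regions on III and IV, with median backgrounds of 2.93 and 2.59 times that mean, count among the low-background regions of all 3 libraries.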
